A study of Mus musculus with 15 samples.

How the data were processed

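The series holds polyA RNA sequencing of mouse embryonic fibroblasts (MEFs) from embryos of day 13.5, cultured in DMEM with 10% fetal bovine serum at 37 °C, 5% CO2 and 3% O2. RNA was extracted with TRIzol, and libraries were made with a NEBNext Ultra kit. All mice lacked mTR (Terc, the RNA template of telomerase) and Wrn (the helicase mutated in Werner syndrome). The fibroblasts called DM carried wild-type p53. Those called TM carried the p53 change N236S on both alleles. Mice without telomerase are bred in successive generations, written G1, G3 and G5, and the series title names the DREAM and MMB complexes and telomere DNA replication. There were 2 libraries each of G1DM, G1TM and G3DM, and 3 each of G3TM, G5DM and G5TM, 15 in all. The design text also names wild-type and p53-mutant control MEFs, which are not analysed here.

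One table of FPKM (fragments per kilobase of gene length, scaled to a fixed library size), deposited by the authors, gave 54495 genes in the 15 libraries. The submitters' processing notes name CASAVA 1.8, fastp, HISAT2 2.0.5, featureCounts 1.5.0-p3 and DESeq2 1.20.0 without giving roles. FPKM times the listed gene length was a whole multiple of one step per library within a tolerance of 0.05 for 100% of values, which gave back read numbers. These recovered reads totalled 17448588 to 29571111 per library, and 19758 to 25789 genes lay above 0. The library size implied by the step was 0.807 to 1.11 times the recovered total, so the authors scaled by something other than the table's total. It followed median-of-ratios size factors of the recovered reads closely (relative ratio 0.984 to 1.02). The step at a length of 1 kilobase, for example 0.0426 FPKM for G1DM replicate 1, is the smallest value above 0 that such a gene could have. A genome build was not given in the sources used here. The gene coordinates equalled those of GENCODE vM21 (GRCm38) for 98.3% of identifiers, and coordinates below are as the table lists them.

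Genes with an FPKM of at least 1 in at least 2 of the 15 libraries were tested, 13562 in all. One linear model with 6 group means was fitted to log2(FPKM + 1) with limma 3.58.1 (R 4.3.3), with empirical Bayes moderation and an intensity trend. Two-sided p-values were adjusted by the Benjamini-Hochberg method, and genes with an adjusted p under 0.05 were called changed. Gene values are given as group mean FPKM with standard deviation (SD), and differences as log2 with standard error (SE). The comparisons were TM against DM in each generation and as the mean of the 3 generations, G3 and G5 against G1 within each genotype, and the interactions, which test whether the TM minus DM difference itself differed from that in G1. These, the filter and the gene lists were chosen before the data were examined. The comparisons of G5 with G3 within DM and within TM were added after the data were seen. A simulation changed 100 genes by 1 log2 unit and 100 by 2 log2 units, drawn from genes above a minimum mean expression. Its noise was independent between genes, and libraries differed only by the changes made. Its rates may therefore not hold for all tested genes or for these libraries. For TM against DM in G1 it recovered 35 changes of 1 log2 unit and 93 of 2 log2 units. The corresponding numbers were 63 and 100 for G5, 95 and 100 for the mean, 46 and 92 for G5 against G1 in DM, and 8 and 77 for the G5 interaction, with 5 to 10 false calls.

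The 23 gene lists with 540 members were DREAM and MMB subunits, G2/M targets of DREAM and MMB, G1/S targets of DREAM and E2F, telomere DNA replication, shelterin and telomerase components, homologous recombination and Fanconi anaemia, p53-activated genes, senescence and its secretory factors, type I interferon response, glycolysis, fibroblast and extracellular matrix, smooth muscle contractile, skeletal muscle, cartilage, macrophage and leukocyte, endothelial, epithelial, neural, erythroid, adipocyte, imprinted growth genes, immediate early genes, and mitochondrially encoded genes. The table held 539 of the members. Lists were tested with camera (limma) with an inter-gene correlation estimated from the residuals, two-sided, adjusted over the 22 lists with tested members. Each list's mean log2(FPKM + 1) per library was also compared between TM and DM by an exact permutation test over all 1200 relabellings within generations, whose smallest two-sided p was 0.000833. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 handled tables and plots.

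Genes were named by a rule. Trp53, Wrn, Terc, Cdkn1a, Mdm2, Cdkn2a, Mybl2 and Foxm1 were always included. The 8 largest rises and 8 largest falls among called protein-coding genes with a group mean FPKM of at least 5 were taken for TM against DM in G5 and as the mean, G5 against G1 in DM, and the G5 interaction. The other comparisons contributed 3 and 3. Up to 3 members of each list with a called member were added. Genes that tell the sex of the embryo were left out of the ranking. Genes named outside the rule are said to have been chosen after their values were seen. Alternatives changed one choice at a time. They covered a pseudocount of 0.1, no filter, a mean FPKM of at least 5, median-ratio scaling, quantile normalization, rescaling to the total of recovered reads, voom on recovered reads, removal of a trend on GC content and gene length, and robust moderation. Others were a fit of only the groups compared, replicate number as a block, sex as a covariate, protein-coding genes only, an adjusted p under 0.01, a fold of at least 2, camera with a preset correlation of 0.01, fry, and leaving out each library. Voom, rescaling, trend removal and a fit without 2 G5DM libraries were chosen after the data were seen. Libraries were also checked for duplicates over genes with at least 50 reads, and none was found (Pearson r within groups, across genes, of 0.922 to 0.990). The labels do not say whether replicates are separate embryos or separate cultures, so p-values measure only the spread between these samples.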

Results

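The targeted genes came first. Wrn (ENSMUSG00000031583, chromosome 8, 33234384 to 33385527) stayed between 0.0447 and 0.599 FPKM in the 15 libraries, below the filter for testing. It measured 0.387 and 0.425 FPKM in G1DM, 0.466 and 0.275 in G1TM, and 0.0824 and 0.0886 in G3DM. In G3TM it measured 0.165, 0.0447 and 0.130 FPKM, in G5DM 0.0802, 0.274 and 0.599, and in G5TM 0.113, 0.196 and 0.118. Terc (ENSMUSG00000064796, chromosome 3, 96414437 to 96414859), which has no polyA tail, was listed at 0 in 14 libraries and at 0.109 FPKM in G5DM replicate 2. Values this low do not show on their own how much of either transcript remained. Trp53 was expressed in every group, from 36.4 ± 3.1 FPKM in G1DM (SD, n = 2) to 81.4 ± 25 in G3TM (SD, n = 3).

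Sex-linked genes divided the libraries cleanly. G1DM replicate 1, the 3 G3TM libraries, G5DM replicates 2 and 3 and G5TM replicate 1 expressed the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty, with a summed FPKM of 2.40 to 34.7. The other 8 libraries expressed Xist, the RNA of the inactive X chromosome, at 2.45 to 28.6 FPKM, and Tsix was listed at 0 in all. In G3 the DM libraries expressed Xist and the TM libraries Y-linked genes, so sex and genotype cannot be told apart there.

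The 6 libraries of G3TM and G5TM stood apart from the other 9. They held 44.7 to 73.6 FPKM of mt-Rnr2, a mitochondrial ribosomal RNA, against 1.48 to 3.76 in the other 9. They also held 73.5 to 102 FPKM of Rrp1, a ribosomal RNA processing factor, against 0.780 to 1.67, and 300 to 610 FPKM of Rpl12, a ribosomal protein, against 3.84 to 6.77. The mitochondrial mRNA mt-Co1 was 839 to 1692 FPKM in the 6 and 3873 to 4916 in the 9. The first principal component held 65.9% of the variance and placed the 6 at 32.2 to 77.5 and the 9 at −71.4 to −11.5. Of the 13562 genes tested, 2325 were higher and 1306 lower in the 6 with no overlap. For a split fixed beforehand, chance gives 0.04% of genes. This split was picked out after the values were seen, so that share is no test of it. Every comparison of TM with DM in G3 and G5, and of G3 or G5 with G1 in TM, spans this division. So do TM against DM as the mean and both interactions. TM against DM in G1 and the generations of DM lie within the 9. The 6 hold TM libraries only, so genotype in G3 and G5 cannot be separated from it.

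**Figure D1:**
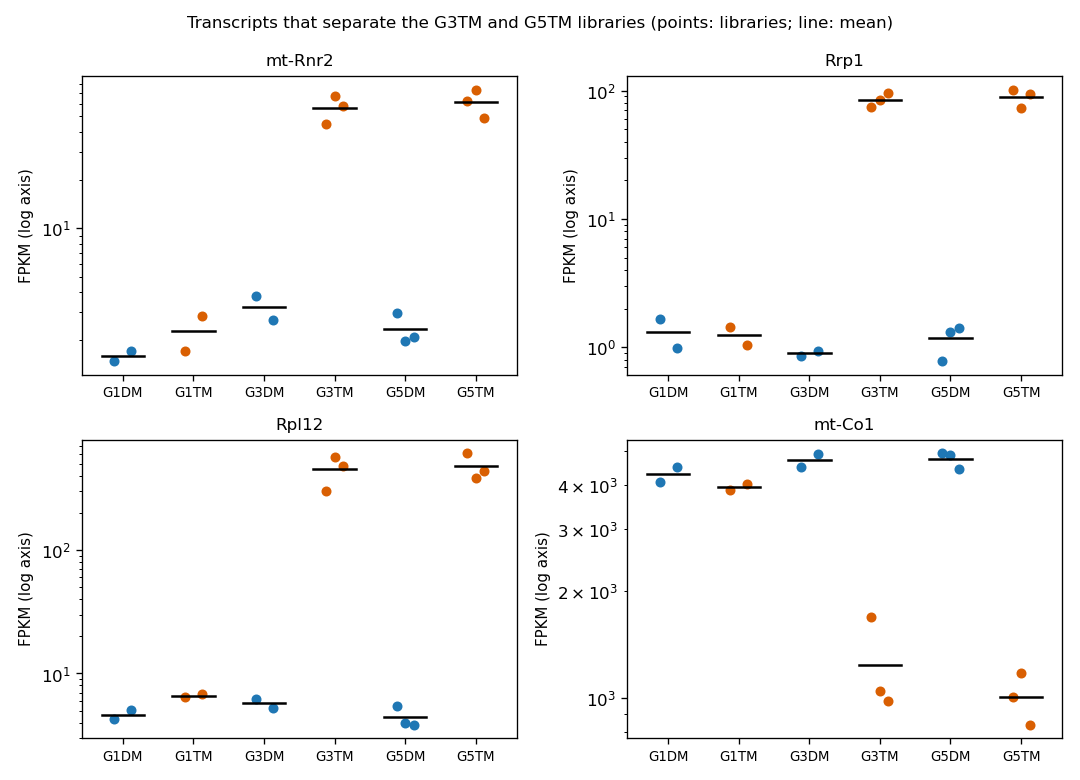
FPKM (log axis) of mt-Rnr2, Rrp1, Rpl12 and mt-Co1 in each library, by group; points are libraries and lines are group means. In the 6 G3TM and G5TM libraries mt-Rnr2 lies at 44.7 to 73.6 and mt-Co1 at 839 to 1692, against 1.48 to 3.76 and 3873 to 4916 in the other 9.

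In G1 fibroblasts, where the genotypes were not divided in that way, some p53 target genes were lower in the p53 mutant. Cdkn1a, which encodes the cell cycle inhibitor p21 (chromosome 17, 29090976 to 29100727), was 113 ± 3.8 FPKM in G1DM and 5.06 ± 1.2 in G1TM (SD, n = 2 each), a log2 difference of −4.25 ± 0.54 (SE, adjusted p = 0.002, limma). Ephx1, an epoxide hydrolase, fell from 117 ± 23 to 8.58 ± 1.4 FPKM (SD, n = 2 each; adjusted p = 0.00012), and the death receptor gene Eda2r from 8.91 ± 1.4 to 0.214 ± 0.036 (adjusted p = 2.7e-05). Both TM libraries lay below both DM libraries for each of these genes. Of 38 measured p53-activated genes, 17 fell, none rose and 21 did not pass. Others that fell were Psrc1 (log2 −2.87 ± 0.21, SE), the antiproliferative gene Btg2 (−2.77 ± 0.24) and Trp53inp1 (−3.30 ± 0.54). Adjusted over the list alone, 30 members fell, and the list's adjusted p with the estimated correlation was 0.000128. That call was lost in a fit of only the groups compared (adjusted p = 0.118, range over 30 alternatives 4.5e-40 to 0.118). Mdm2, which encodes the ubiquitin ligase that degrades p53, was 33.8 ± 12 FPKM in DM and 9.47 ± 0.61 in TM and did not pass (adjusted p = 0.087), although it did without G3TM replicate 1 (adjusted p = 0.0388). Neither did Trp53 itself (log2 0.38 ± 0.35, adjusted p = 0.80) or Cdkn2a (−0.92 ± 0.68, adjusted p = 0.71).

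Some cell cycle genes rose in G1. Pttg1 (securin) rose by 1.54 ± 0.23 on the log2 scale (SE, adjusted p = 0.0053), the mitotic kinase gene Aurkb by 1.35 ± 0.25 (adjusted p = 0.023) and Pimreg by 1.52 ± 0.29 (adjusted p = 0.025), each higher in both TM libraries than in both DM libraries. Of 62 G2/M targets of DREAM and MMB, 10 rose, none fell and 52 did not pass, and 52 rose adjusted over the list alone. Of 52 G1/S targets, 6 rose, none fell and 46 did not pass, and 48 rose adjusted over the list alone. The 6 included the polymerase gene Pole (1.23 ± 0.25, adjusted p = 0.033). In homologous recombination and Fanconi anaemia 5 of 32 rose, 27 did not pass, and 12 rose adjusted over the list alone, with Eme1 (1.15 ± 0.23) and Fancd2 (0.97 ± 0.20) among the 5. No telomere DNA replication gene passed over all genes (0 of 32 with limma, 25 adjusted over the list alone, all higher). With the estimated correlation, the adjusted p was 0.0816 for the G2/M, G1/S and telomere replication lists and 0.104 for homologous recombination, so none of these lists was called. After removal of the trend on GC content and gene length, a correction chosen after the data were seen, 29 G2/M, 20 G1/S, 11 telomere DNA replication and 9 homologous recombination genes changed over all genes, and the lists were still not called (adjusted p 0.112 to 0.117).

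Foxm1 and Mybl2, both in the list of DREAM and MMB subunits, were higher in G1TM without passing. Foxm1 was 32.1 ± 1.5 FPKM in TM and 13.1 ± 5.2 in DM (SD, n = 2 each; adjusted p = 0.051), and Mybl2 (B-Myb) was 12.4 ± 2.8 and 3.66 ± 2.2 (adjusted p = 0.14). Foxm1 passed under 12 of 28 alternatives (adjusted p 0.0235 to 0.426), among them the fits without G1DM replicate 2 (0.0245), G5DM replicate 1, 2 or 3 (0.0391, 0.0435 and 0.0474) or G5TM replicate 2 (0.0483). None of the 14 DREAM and MMB subunits passed over all genes, and 5 did adjusted over the list alone (adjusted p of the list 0.106 with the estimated correlation). Other named changes were a rise of the histone genes Hist1h2ao (2.85 ± 0.61, SE, adjusted p = 0.041) and Hist1h2ap (2.30 ± 0.38, adjusted p = 0.011). The smooth muscle myosin gene Myh11 fell by 2.13 ± 0.38 (adjusted p = 0.018), while the endothelial receptor gene Flt1 (1.25 ± 0.26, adjusted p = 0.039) and the glycolytic gene Hk2 (1.35 ± 0.30, adjusted p = 0.048) rose. In all, 159 genes changed in G1, 49 higher and 110 lower in TM. The count rested on single libraries: it was 21, none of them higher, without G1TM replicate 1, 25 without G1TM replicate 2, 39 without G1DM replicate 1, 262 without G1DM replicate 2, and 355 without G5DM replicate 1, which enters through the shared spread. Cdkn1a, Ephx1, Eda2r, Psrc1 and Btg2 kept their calls in every fit that left out 1 library. The calls of all other genes named here for G1 were lost without G1TM replicate 1 or 2, and without G1DM replicate 1, as Aurkb shows (adjusted p = 0.17, 0.255 and 0.226; range over 28 alternatives 0.00578 to 0.255). Myh11 and Flt1 were also lost without G1DM replicate 2, and Pole, Fancd2, Hist1h2ao, Flt1 and Hk2 also without at least 1 library of another generation.

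**Figure D2:**
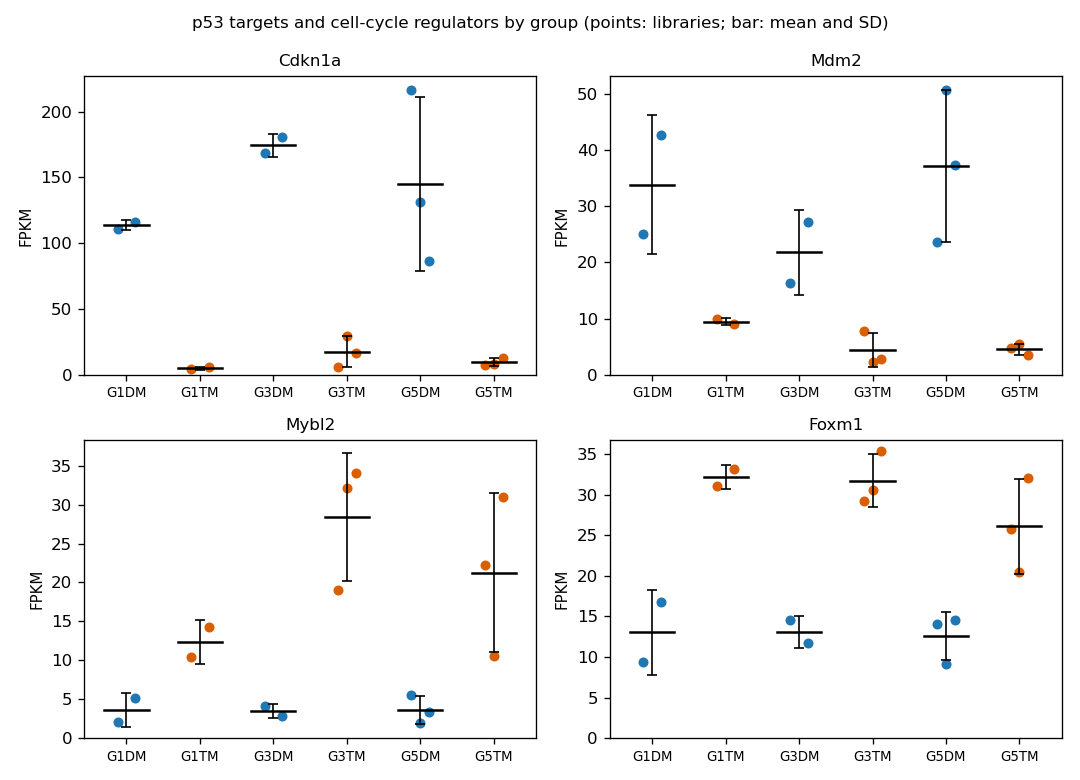
FPKM of Cdkn1a, Mdm2, Mybl2 and Foxm1 by group; points are libraries, and bars with whiskers are group means with SD (n = 2 or 3). Cdkn1a lies at 4.22 to 29.6 in the 8 TM libraries and 86.2 to 216 in the 7 DM libraries, and Mybl2 at 10.4 to 34.0 and 1.91 to 5.55.

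Averaged over the 3 generations, the same p53 targets were low in every TM library. Ccng1 (cyclin G1) was 3.94 to 23.0 FPKM in TM and 80.9 to 326 in DM (adjusted p = 1.5e-08). Cdkn1a differed by a log2 of −3.83 ± 0.28 (SE, adjusted p = 9.2e-07), and Perp, an apoptosis effector, by −3.45 ± 0.29 (adjusted p = 2.7e-06). Ephx1 (−3.41 ± 0.17) and Eda2r (−3.13 ± 0.12) behaved likewise, and in all of these genes the 8 TM libraries lay below the 7 DM libraries without overlap. Mdm2 fell by 2.20 ± 0.24 on the log2 scale (adjusted p = 1.4e-05), at 2.33 to 9.90 FPKM in TM against 16.4 to 50.6 in DM. Of the 38 p53-activated genes, 27 fell, 1 rose and 10 did not pass, and 28 changed adjusted over the list alone (adjusted p of the list 0.0133 with the estimated correlation). That list was not called without G3TM replicate 1 (adjusted p = 0.0509) or without G5DM replicate 1 (0.0851), and over 30 alternatives its adjusted p ran from 1.2e-12 to 0.0851. Trp53 was higher in TM by 0.61 ± 0.18 (adjusted p = 0.014), with overlapping libraries, and this call was lost with quantile normalization (0.22, adjusted p = 0.102, range over 28 alternatives 0.00284 to 0.102). Cdkn2a, which encodes p16 and p19Arf, did not pass (0.16 ± 0.36, adjusted p = 0.72).

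Many proliferation and DNA replication genes were higher in TM. Mybl2 rose by 2.16 ± 0.26 (SE, adjusted p = 3.0e-05) and Foxm1 by 1.17 ± 0.15 (adjusted p = 5.9e-05), and neither overlapped between the 8 TM and 7 DM libraries (Foxm1 20.4 to 35.4 against 9.15 to 16.8 FPKM). Of 14 DREAM and MMB subunits 7 rose, 1 fell (Rbl2, the repressive pocket protein p130, −0.93 ± 0.15) and 6 did not pass, with 8 changed adjusted over the list alone (adjusted p 0.555 with the estimated correlation). Among 62 G2/M targets 48 rose, 1 fell and 13 did not pass (49 adjusted over the list alone), including Pimreg (2.04 ± 0.15), Cks2 (1.75 ± 0.15) and Aurkb (1.66 ± 0.13). Among 52 G1/S targets 47 rose and 5 did not pass (47 adjusted over the list alone), including Cdc45, a part of the replicative helicase (1.65 ± 0.15), and the thymidine kinase gene Tk1 (1.94 ± 0.20). Of 32 telomere DNA replication genes 25 rose and 7 did not pass (25 adjusted over the list alone), including Pold2, a subunit of DNA polymerase delta (2.46 ± 0.20, adjusted p = 2.1e-06), Timeless (1.30 ± 0.12) and the clamp loader gene Rfc4 (1.41 ± 0.14). With the estimated correlation the adjusted p was 0.421 for the G2/M and the G1/S lists and 0.323 for telomere DNA replication. Shelterin and telomerase components had 9 of 16 higher, 1 lower and 6 that did not pass (10 adjusted over the list alone; adjusted p 0.207 with the estimated correlation), led by Gar1 (1.69 ± 0.16), a protein of box H/ACA particles. Of 32 homologous recombination and Fanconi anaemia genes 15 rose and 17 did not pass (15 adjusted over the list alone; adjusted p 0.521 with the estimated correlation), with Eme1 (1.47 ± 0.12) and Rad54l (0.93 ± 0.10) first. In all 7339 genes changed, 3934 higher and 3405 lower in TM, a mean to which G3 and G5 contribute across the division of the 6 and 9 libraries.

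The exact permutation test of list means, which compares the lists with no other genes, gave a mean TM minus DM difference of −1.37 log2 units for p53-activated genes (p = 0.000833, the smallest it can give, adjusted p = 0.00367 over 22 lists). All 8 TM libraries lay below all 7 DM libraries. The same p and adjusted p went with G1/S targets (0.96), telomere DNA replication (0.89), shelterin and telomerase components (0.66) and endothelial genes (−0.35). In the same permutation test G2/M targets were higher by 0.93 (p = 0.00167, adjusted p = 0.00524). It also passed the DREAM and MMB, homologous recombination, senescence, glycolysis, fibroblast, smooth muscle, neural, imprinted and mitochondrially encoded lists (adjusted p 0.00524 to 0.0208). The test therefore does not single out the p53, cell cycle and replication lists. In G3 and G5 it spans the division of the 6 and 9 libraries. With camera's preset correlation many lists were called. With the estimated correlation only the p53-activated genes held, in G1, in G3 and as the mean. After removal of the trend on GC content and gene length, a correction chosen after the data were seen, they were called in G5 too (adjusted p = 0.0375).

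**Figure D3:**
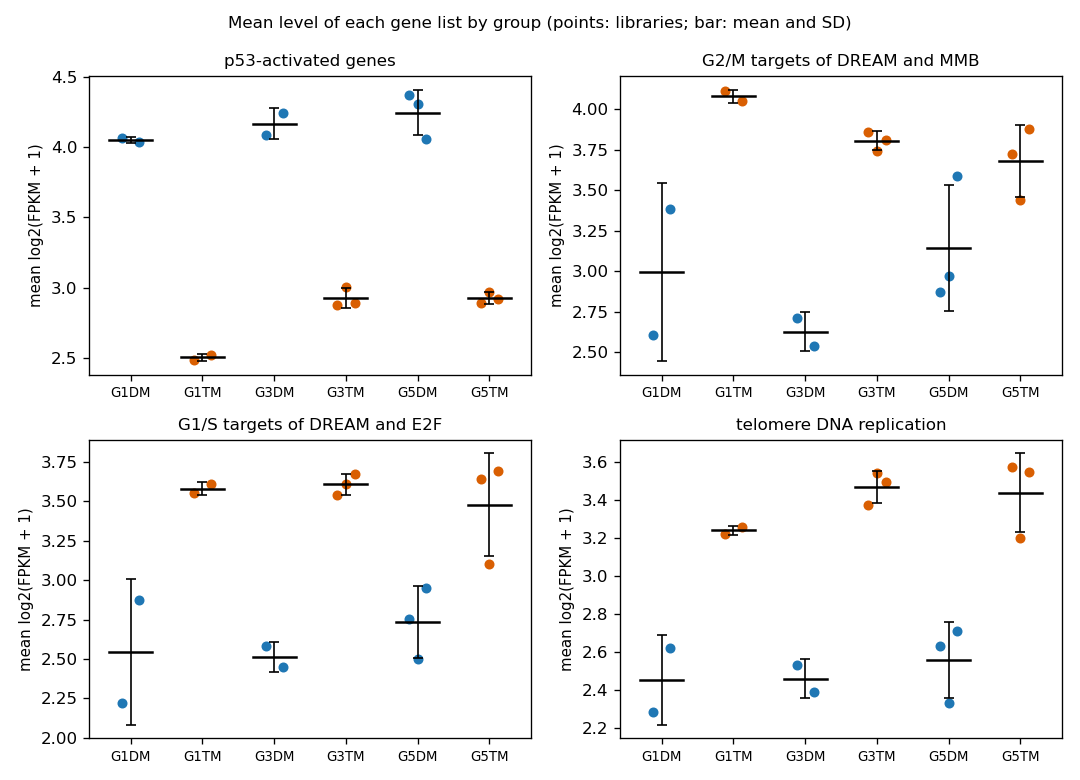
Mean log2(FPKM + 1) of the p53-activated, G2/M, G1/S and telomere DNA replication lists in each library, by group; points are libraries and bars group means. The p53-activated list has group means of 4.05, 4.16 and 4.24 in G1DM, G3DM and G5DM, and 2.50, 2.92 and 2.93 in G1TM, G3TM and G5TM.

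Agreement between generations was counted over called genes. Of the 49 genes higher in TM in G1, 32 were also higher in G3 (8.84 would be if the calls were independent), and of the 110 lower genes 96 were also lower (15.3). In G5 the counts were 31 (14.9) and 84 (31.2). These generations share no libraries, although one estimate of the spread serves all. In all 3 generations 28 genes were higher and 79 lower. Of these 107, 16 are p53-activated genes of the list, among them Cdkn1a, Ccng1, Perp, Fas, Pmaip1 and Zmat3, and the higher ones include Aurkb, Bub1b, Cdc45 and Mcm6. These examples were picked after their values were seen.

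In G3, the p53 targets Ccng1 (−3.88 ± 0.33, SE, adjusted p = 8.7e-06), Cdkn1a (−3.50 ± 0.49, adjusted p = 0.00032) and Mdm2 (−2.19 ± 0.41, adjusted p = 0.0019) fell in TM, each lower in all 3 TM libraries than in both DM libraries. Mybl2 (2.67 ± 0.44) and Foxm1 (1.21 ± 0.26) rose, the latter not without G3DM replicate 2 (adjusted p = 0.0639, range over 27 alternatives 0.00299 to 0.0639). Of the p53-activated genes 24 fell, 1 rose and 13 did not pass (25 adjusted over the list alone; adjusted p 0.0248 with the estimated correlation). G2/M targets had 40 of 62 higher and 22 that did not pass (45 adjusted over the list alone), G1/S targets 35 of 52 higher and 17 that did not pass (44), and telomere DNA replication 22 of 32 and 10 (23), with adjusted p of 0.373, 0.373 and 0.370 with the estimated correlation. The largest rises among protein-coding genes with a group mean FPKM of at least 5 were Rpl12 (6.03 ± 0.27), Rrp1 (5.49 ± 0.21) and the chaperone gene Hsp90aa1 (5.20 ± 0.27), which also part the 6 libraries from the other 9. All 13 mitochondrially encoded genes fell (13 adjusted over the list alone; adjusted p 0.143 with the estimated correlation), among them mt-Co1, which was low in the 6 libraries. Skeletal muscle genes had 8 of 11 higher, 1 lower and 2 that did not pass (10 adjusted over the list alone; adjusted p 0.640 with the estimated correlation), and G3TM replicates 2 and 3 carried the rise: Myog, a muscle transcription factor, was 61.6 and 15.7 FPKM there and 0.737 in replicate 1. In total 4336 genes changed, 2446 higher and 1890 lower. That number fell to 1552 without G3DM replicate 2 and 2436 without G3DM replicate 1, and the list call of p53-activated genes was lost without G1DM replicate 1 or 2 (adjusted p = 0.054 each), G3TM replicate 1 (0.0841) or G5DM replicate 1 (0.0876), over a range of 9.3e-11 to 0.208 in 29 alternatives.

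In G5, Ccng1 was 257 ± 67 FPKM in DM and 6.10 ± 0.97 in TM (SD, n = 3 each), a log2 difference of −5.16 ± 0.30 (SE, adjusted p = 1.8e-07). Cdkn1a was 145 ± 66 and 9.40 ± 2.9 FPKM (log2 −3.74 ± 0.44, adjusted p = 4.0e-05). The proapoptotic gene Pmaip1 (Noxa) fell by 3.54 ± 0.24 and Mdm2 by 2.73 ± 0.37. Mybl2 rose by 2.23 ± 0.40 (adjusted p = 0.00056) and Foxm1 by 1.00 ± 0.24 (adjusted p = 0.0032), higher in all 3 TM than in all 3 DM libraries. Of the p53-activated genes 27 fell, 5 rose and 6 did not pass (32 adjusted over the list alone; adjusted p 0.0921 with the estimated correlation, 0.0375 after that removal of the trend). G2/M targets had 33 higher, 6 lower and 23 that did not pass (40 adjusted over the list alone). G1/S targets had 30, 2 and 20 (33), and telomere DNA replication 21, 1 and 10 (23), the last led by Pold2 at 140 ± 30 against 12.0 ± 5.5 FPKM. Their adjusted p with the estimated correlation was 0.698, 0.609 and 0.609. Of the 14 DREAM and MMB subunits 5 rose, 4 fell and 5 did not pass (9 adjusted over the list alone; adjusted p 0.992). Their mean log2 difference was 0.15, their median −0.14 and the direction of the camera test down.

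Cdkn2a rose in G5 by 1.77 ± 0.56 (SE, adjusted p = 0.016), but its TM libraries held 114, 144 and 34.9 FPKM against 34.0, 25.6 and 15.3 in DM. The call was lost without G5DM replicate 3, G5TM replicate 1 or G5TM replicate 2 (adjusted p = 0.0678, 0.0634 and 0.0689; range over 28 alternatives 0.00352 to 0.446). Trp53 rose by 0.84 ± 0.29 (adjusted p = 0.022), a call lost without G5DM replicate 2 or 3 (adjusted p = 0.0949 and 0.0761) or G5TM replicate 1 or 3 (0.0672 and 0.0906; range over 28 alternatives 0.00432 to 0.54). Of 28 fibroblast and extracellular matrix genes 14 fell, 3 rose and 11 did not pass, and those that fell included decorin (Dcn, −3.11 ± 0.36) and lumican (Lum, −3.46 ± 0.41). Glycolysis genes had 12 of 18 higher and 6 that did not pass, led by Pfkl (1.75 ± 0.27), and 7 of 8 cartilage genes were higher, led by Acan (2.98 ± 0.44) and Col2a1 (2.53 ± 0.41), which encode cartilage matrix proteins. Adjusted over the list alone the changed members were 17, 12 and 7, and all 3 lists had an adjusted p of 0.609 with the estimated correlation. Among protein-coding genes with a group mean FPKM of at least 5, the largest rises, Rpl12 (6.45 ± 0.24) and Rrp1 (5.38 ± 0.19), again follow the division of the 6 and 9 libraries. The fall of mt-Nd4l (−3.79 ± 0.24) does so too. The falls of Cdkn1a, Eda2r (−3.61 ± 0.18) and Perp (−3.46 ± 0.45) were about as large. These 3 genes overlapped between the 6 and the 9, but not between the 8 TM and 7 DM libraries. In all 7962 genes changed, 4114 higher and 3848 lower. The balance depended on the filter and the scaling, at 2987 higher and 1589 lower with a mean FPKM of at least 5, 3936 and 4832 with no filter, and 3575 and 4471 after rescaling to recovered reads, which was chosen later. Without the G5DM libraries with high Malat1 (replicates 2 and 3, 314 and 322 FPKM against 29.6), a fit chosen after the data were seen, 2932 changed and Foxm1 did not pass (adjusted p = 0.0782, range over 28 alternatives 0.002 to 0.0782).

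The remaining lists were read as the mean of 3 generations, across the same division. Senescence and its secretory factors had 12 of 27 lower, 2 higher and 13 that did not pass (14 adjusted over the list alone; adjusted p 0.521 with the estimated correlation), such as the chemokine gene Ccl7 (−1.57 ± 0.28, SE) and the adhesion gene Icam1 (−1.66 ± 0.23). Fibroblast and extracellular matrix genes had 15 of 28 lower, 2 higher and 11 that did not pass (18; 0.421). Glycolysis had 12 of 18 higher and 6 that did not pass (12; 0.521). Endothelial genes had 5 of 7 lower, 1 higher and 1 that did not pass (7; 0.421), and smooth muscle genes 4 of 12 lower and 8 that did not pass (4; 0.555), led by Myh11 (−2.28 ± 0.20). Imprinted growth genes had 7 of 16 lower, 1 higher and 8 that did not pass (8; 0.555), with Igf2r, which clears the growth factor IGF2, at −1.72 ± 0.12. Immediate early genes had 8 of 17 higher, 2 lower and 7 that did not pass (11; 0.764). In each pair of parentheses the first number is the count changed adjusted over the list alone and the second the adjusted p with the estimated correlation.

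Type I interferon response genes had 3 of 25 higher, 3 lower and 19 that did not pass (6 adjusted over the list alone; adjusted p 0.916 with the estimated correlation). In the same order of counts, skeletal muscle had 5 of 11 higher, 1 lower and 5 that did not pass (8; 0.764). Cartilage genes had 2 of 8 higher, 1 lower and 5 that did not pass (3; 0.764), and so had epithelial genes (3; 0.777), such as the keratin gene Krt19 (1.15 ± 0.22, SE). Neural genes had 3 of 9 higher and 6 that did not pass (3; 0.555), such as Tubb3 (1.68 ± 0.25), and adipocyte genes 2 of 4 higher and 2 that did not pass (3; 0.695). None of 14 macrophage and leukocyte genes passed (0 with limma, 0 adjusted over the list alone; adjusted p 0.844). The table held 11 erythroid genes, and none passed the filter. Mitochondrially encoded genes had 12 of 13 lower (13; 0.212), and mt-Co1 was 839 to 1692 FPKM in the 6 G3TM and G5TM libraries against 3873 to 4916 in the other 9.

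From G1 to G3 in DM, the gene of the peptide hormone cholecystokinin, Cck, rose from 10.4 ± 7.0 to 186 ± 130 FPKM (SD, n = 2 each; log2 4.01 ± 0.46, SE, adjusted p = 0.0046). The cholesterol exporter gene Abcg1 rose from 1.40 ± 0.26 to 9.80 ± 1.2 FPKM (2.17 ± 0.27, adjusted p = 0.0081), and the aryl hydrocarbon receptor gene Ahr fell from 16.4 ± 3.0 to 4.20 ± 1.1 (−1.75 ± 0.31, adjusted p = 0.040). For each of these, both G3DM libraries lay on one side of both G1DM libraries. Of 7 endothelial genes 2 rose and 5 did not pass (2 adjusted over the list alone), Esam (1.34 ± 0.23) and Cdh5 (1.11 ± 0.19), and 5 of 8 epithelial genes were higher adjusted over the list alone (0 over all genes). Every list had an adjusted p of 0.983 with the estimated correlation. In all 29 genes changed, 25 higher and 4 lower, a direction that turned with no filter on expression (47 higher, 71 lower) and without the G5DM libraries with high Malat1 (248 and 1100, a fit chosen after the data were seen). That count was 2 to 18 without any single G1 library, either G3DM library, G3TM replicate 2 or 3, or G5TM replicate 1 or 3. It was 77 without G3TM replicate 1 and 1533 (329 higher, 1204 lower) without G5DM replicate 1. Cck was lost without G1DM replicate 1 (adjusted p = 0.0606, range over 28 alternatives 0.00109 to 0.0716). Abcg1 was lost without G1DM replicate 1 or G3DM replicate 1 or 2 (0.0933, 0.126 and 0.0679; range over 27 alternatives 0.00283 to 0.126). Ahr, Esam and Cdh5 were lost without either G3DM library, G1DM replicate 1 or several libraries of other groups.

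From G1 to G5 in DM, the limb and posterior patterning gene Hoxc10 fell from 5.49 ± 1.7 to 0.304 ± 0.47 FPKM (SD, n = 2 and 3; log2 −2.35 ± 0.32, SE, adjusted p = 0.015). The histone gene Hist1h4m fell from 5.01 ± 0.030 to 0.226 ± 0.052 FPKM (−2.29 ± 0.19, adjusted p = 0.00028) and Ahr from 16.4 to 4.10 ± 0.65 (−1.77 ± 0.28, adjusted p = 0.041). Abcg1 rose to 6.80 ± 1.9 FPKM (1.68 ± 0.25, adjusted p = 0.028). All 3 G5DM libraries lay on one side of both G1DM libraries for these genes. Cdkn1a (0.25 ± 0.49), Mdm2 (0.12 ± 0.41), Mybl2 (−0.01 ± 0.44) and Foxm1 (−0.02 ± 0.26) did not pass. None of the 62 G2/M, 52 G1/S and 32 telomere DNA replication genes passed with limma, nor adjusted over each list alone, and the lists' adjusted p was 0.942, 0.885 and 0.942 with the estimated correlation. The 38 p53-activated genes had no called member either (0.501). Immediate early genes had 9 of 17 lower adjusted over the list alone and 0 over all genes (adjusted p 0.299). In all 8 genes changed, 1 higher and 7 lower, and 689 had an unadjusted p under 0.05. The count was 4 or 5 without any single G1 library, G3TM replicate 2, G5DM replicate 2 or G5TM replicate 3, 16 without G5DM replicate 3, and 132 (100 higher, 32 lower) without G5DM replicate 1. Hist1h4m kept its call in every fit that left out 1 library. Hoxc10 was lost without G1DM replicate 1 or 2 (adjusted p = 0.246 and 0.063; range over 28 alternatives 0.00316 to 0.355). Ahr and Abcg1 were lost without either G1DM library, G5DM replicate 2 or several libraries of other groups.

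From G3 to G5 in DM, a comparison added after the data were seen, 676 genes changed, 454 higher and 222 lower, and 309 did (172 and 137) after removal of the trend on GC content and gene length. Of 62 G2/M targets 6 rose and 56 did not pass (14 adjusted over the list alone), and of 8 epithelial genes 4 fell and 4 did not pass (7 adjusted over the list alone), both with an adjusted p of 0.720 with the estimated correlation.

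The comparisons of G3 and G5 with G1 within TM set the 6 libraries against 2 of the other 9. Cdkn1a was 5.06 ± 1.2 FPKM in G1TM and 17.3 ± 12 in G3TM (SD, n = 2 and 3; log2 1.37 ± 0.49, SE, adjusted p = 0.035), and 9.40 ± 2.9 in G5TM (n = 3), which did not pass (0.76 ± 0.49, adjusted p = 0.21). The first of these calls was lost without G1TM replicate 1 or 2 (adjusted p = 0.2 and 0.0747) or G3TM replicate 2 or 3 (0.137 and 0.0882; range over 27 alternatives 0.00199 to 0.2). Bax, a proapoptotic p53 target, rose by 2.77 ± 0.33 in G3 (adjusted p = 0.00013) and 3.02 ± 0.33 in G5 (adjusted p = 5.3e-05). The p53-activated genes had 14 higher, 5 lower and 19 that did not pass in G3 (20 adjusted over the list alone) and 13, 4 and 21 in G5 (17). Foxm1 did not pass in either (−0.02 ± 0.26 and −0.31 ± 0.26), nor did Mybl2 (1.11 ± 0.44 and 0.63 ± 0.44). G2/M targets had 10 higher, 21 lower and 31 that did not pass in G3 (33 adjusted over the list alone) and 6, 22 and 34 in G5 (27), with Aspm, a spindle protein gene, at −1.67 ± 0.37 (lost without G1TM replicate 1, adjusted p = 0.0629) and −1.86 ± 0.37. The histone gene Hist1h2ao fell by 6.10 ± 0.56 and 4.85 ± 0.56, while Rpl12 rose by 5.85 ± 0.27 and 5.95 ± 0.27. Of the mitochondrially encoded genes 12 of 13 fell in each (13 and 12 adjusted over the list alone). With the estimated correlation no list was called, at adjusted p of 0.619 or more in G3 and 0.835 or more in G5. In G3 6350 genes changed (3415 higher, 2935 lower) and in G5 6718 (3527 and 3191). Without G1TM replicate 1 the counts were 1775 and 2900, and G3 against G1 gave 4138 without G1TM replicate 2 and 4225 without G3TM replicate 2. Between G3 and G5 within TM, a comparison added later and inside the 6 libraries, 4 genes changed, 3 higher and 1 lower, with 381 at an unadjusted p under 0.05.

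The interaction asks whether the genotype difference itself differed from that in G1, and it spans the division of the 6 and 9 libraries. For Cdkn1a (0.51 ± 0.69 in G5, SE, adjusted p = 0.60), Mdm2 (−1.04 ± 0.58, adjusted p = 0.19), Mybl2 (0.64 ± 0.63, adjusted p = 0.46) and Foxm1 (−0.29 ± 0.37, adjusted p = 0.58) it did not pass. For Ccng1 it did (−2.21 ± 0.47, adjusted p = 0.010), a call lost without G1DM replicate 1 or G1TM replicate 1 (adjusted p = 0.0504 and 0.062; range over 28 alternatives 0.00209 to 0.0936). Bax (2.63 ± 0.46) and Bbc3 (Puma, 2.68 ± 0.53), proapoptotic p53 targets, had a positive interaction in G5: Bax was 39.4 ± 0.13 FPKM in G1DM and 20.6 ± 2.4 in G1TM (SD, n = 2 each), but 55.7 ± 27 in G5DM and 175 ± 26 in G5TM (n = 3 each). Bax also parted the 6 G3TM and G5TM libraries (102 to 203 FPKM) from the other 9 (18.9 to 86.7) without overlap, while Bbc3 overlapped. Of the 38 p53-activated genes 6 had a positive and 3 a negative interaction and 29 did not pass (10 adjusted over the list alone). Cartilage genes had 5 of 8 positive and 3 that did not pass (8 adjusted over the list alone), with Col2a1 at 4.23 ± 0.65 (adjusted p = 0.0022). Homologous recombination and Fanconi anaemia genes had 6 of 32 negative and 26 that did not pass (14 adjusted over the list alone), among them Brca1 (−1.25 ± 0.37) and Rad50 (−1.38 ± 0.40), each lost without several single libraries. Among protein-coding genes with a group mean FPKM of at least 5, the largest were Rpl12 (6.02 ± 0.38), Rrp1 (5.43 ± 0.29) and Hist1h2ao (−5.34 ± 0.79), and 12 of 13 mitochondrially encoded genes were negative. With the estimated correlation the adjusted p of every list was 0.515 or more. In total 2683 genes passed for G5 (1553 positive, 1130 negative) and 328 for G3 (208 and 120), with Bax (2.11 ± 0.49, adjusted p = 0.041) and Cks2 (1.70 ± 0.40, adjusted p = 0.042) among the latter, both lost without most single libraries of G1 and G3. The G5 count was 858 and 1686 without G1DM replicates 1 and 2, 429 and 880 without G1TM replicates 1 and 2, 5756, 1105 and 1385 without G5DM replicates 1, 2 and 3, and 1429 and 1680 without G5TM replicates 1 and 3. The G3 count was 80 to 179 without any single library of G1 or G3 other than G3TM replicate 1, 1088 without that one, and 814 without G5DM replicate 1.

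**Figure D4:**
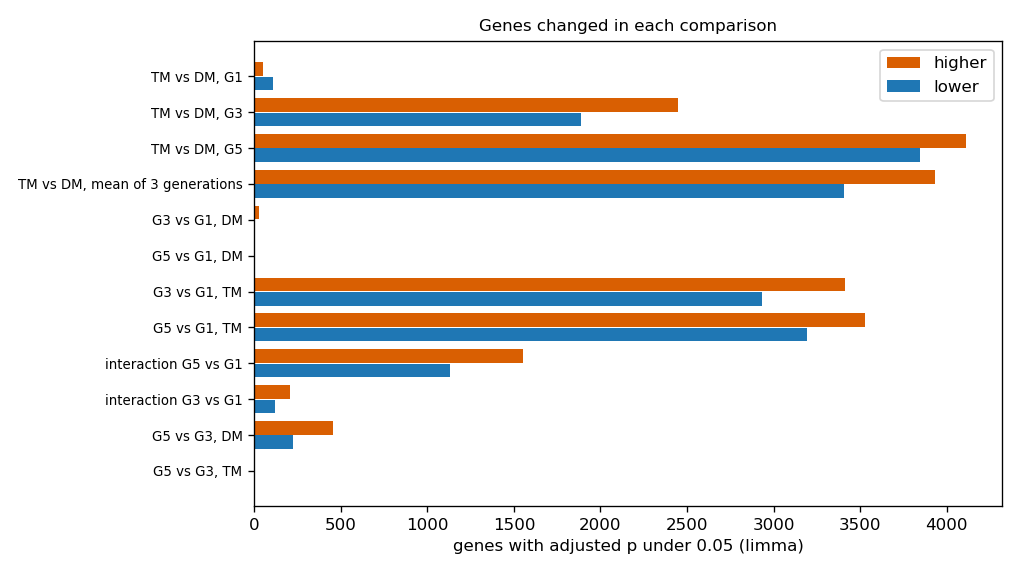
Number of genes higher and lower (bars) in each comparison at an adjusted p under 0.05, of 13562 tested. The contrasts within the 9 libraries call 8 to 676 genes and those that span the 6 G3TM and G5TM libraries 328 to 7962, while G5 against G3 in TM, inside the 6, calls 4.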

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

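The tests of ribosome biogenesis, of depth, of the trend on GC content and gene length for the counts and in G5DM, and of embryo sex were chosen after the results they bear on were seen. So were the correction for that trend, the comparison of G5 with G3 in TM, and the fit without G5DM replicates 2 and 3.

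The difference between TM and DM in G5 was itself unlike that in G1 for 2683 genes by the interaction test, and that in G3 for 328. For Cdkn2a the interaction in G5 was 2.69 ± 0.88 (SE, adjusted p = 0.049, limma). Cdkn2a was 41.7 ± 4.0 FPKM in G1DM and 21.5 ± 1.2 in G1TM, (SD, n = 2 each), against 34.0, 25.6 and 15.3 in the G5DM libraries and 97.6 ± 56 in G5TM (SD, n = 3). That call was lost under 17 of 28 alternatives, including the fits without any single library of G1, without either G3DM library (0.0622 each) and without G5DM replicate 2 or 3 (0.0877 and 0.102) or G5TM replicate 1 or 2 (0.101 and 0.0841). It was also lost after removal of the trend on GC content and gene length (adjusted p = 0.356, log2 1.47), and over all alternatives its adjusted p ran from 0.0176 to 0.356.

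Other splits of the libraries were compared with the real ones. For TM against DM as the mean of 3 generations, 1 of 100 splits within generations gave as many genes, the real one. It gave 7339 genes and the highest other 9, so a random split does not give such a count. Within G5, 1 of 10 splits gave as many (7962 genes, highest other 0), and 10 splits are too few for a share under 0.05. In both tests every other split mixed the G3TM or G5TM libraries with DM libraries of the same generation. The low counts of the other splits may therefore come from the division of the libraries described above. These tests cannot tell genotype from that division. For G5 against G3 in TM, 3 of 10 splits gave at least the 4 genes of the real one, again too few splits. The split of G3TM replicate 1 with G5TM replicates 1 and 2 against the rest gave 132, which points to a structure among these libraries other than generation. The rest, G3TM replicates 2 and 3 and G5TM replicate 3, are the 3 libraries with the highest means of the skeletal muscle and the macrophage and leukocyte lists. Whether such genes account for the 132 was not tested.

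More genes differed between TM and DM in G5 (7962) than in G1 (159), and 3 technical explanations were tested. Unequal numbers of libraries, 3 per genotype in G5 and 2 in G1, were not among them. In the simulation, 63 of 100 changes of 1 log2 unit were recovered in G5 and 35 in G1. The G5 count was 6070 or more when any 1 library was left out. A higher depth of the G5 libraries would give more calls. Its test asked for full separation and left it open, as libraries overlapped (17.4 to 25.9 M recovered reads in G5 and 22.4 to 29.6 M in G1). The mean was lower in G5 (20.01 M against 24.34 M), however. Every G5 library but G5DM replicate 3 held 17.4 to 20.1 M, below every G1 library. These values argue against a higher depth in G5. A trend on GC content and gene length was argued against as the whole cause, since after its removal 6668 genes changed in G5 (4914 or more when each library was left out) and 423 in G1 (33 to 594, the lowest without G1TM replicate 2). How much of the interaction it explains stayed open: interactions numbered 2683 before its removal and 1398 after, of which 1026 were among the 2683 with the same direction, and the second count was 52.1% of the first, or 48.3 to 76.0% when each library was left out, which spans the bound of 1 in 2 set beforehand. Different handling of the 6 G3TM and G5TM libraries is consistent with the 4 genes that differed between G5 and G3 within TM, against 6718 between G5 and G1 in TM, but the same numbers would arise if G3TM and G5TM cells were alike for biological reasons, generation and genotype among them, which was not tested because the 6 libraries hold no DM.

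Genes named for ribosomal RNA processing, such as Rrp1, Rrp7a and Rrp12, were higher in the 6 G3TM and G5TM libraries apart from Esf1 (−0.86), with a median log2 difference of 2.76 over 10 genes (interquartile range 1.68 to 3.79), and 8 of the 10 did not overlap with the other 9 libraries, while 2325 of all 13562 genes tested were higher without overlap. More ribosome biogenesis in the cells predicts a like rise in other such genes, but 61 of these had a median of 0.286 (interquartile range −0.18 to 1.03). That comparison cannot decide, since the 10 genes were grouped after some were seen to be high. In addition, 47 ribosomal protein genes of the large subunit (names starting Rpl) had a median of 1.48, with 35 higher without overlap and 0 lower, so this explanation stayed open. Genes of the small subunit (Rps) were not in that set. A candidate explanation is that reads of ribosomal RNA genes and of genes with such names were handled differently in the 2 sets of libraries, for example by a filter on names. Its test, 6 genes whose older symbols start with Rrp, left it open: their median was 1.11, but their lower quartile of −0.24 lay below the upper quartile of the other genes. Such handling would not cover Rpl12 (300 to 610 FPKM in the 6, 3.84 to 6.77 in the 9) or Hsp90aa1 (40.4 to 73.2 and 0.557 to 2.09). These carry no such name and also parted the 2 sets. A biological difference between the 6 and the 9, which differ in genotype and generation, was not tested further.

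G5DM replicate 1 stood apart from G5DM replicates 2 and 3, with a mean correlation across genes (not independent replicates) of 0.179 with these and 0.370 with the G3DM libraries, after centring each gene. The trend on GC content and gene length was argued against as the whole cause: after its removal the values were 0.247 (highest 0.353) and 0.364 (lowest 0.364), still without overlap. A difference in embryo sex stayed open: over 13095 genes off the sex chromosomes, the Xist minus Y-linked difference in G5DM correlated at −0.310 with that in G5TM, where a shared sex effect needs a positive value, but each difference rests on 1 library on one side. This test replaced one on correlations without the sex chromosomes (0.181 with replicates 2 and 3, 0.367 with G3DM) after its values were seen. No other biological explanation was tested, as the labels name none within a group.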

How the results depend on the processing

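Voom, rescaling to recovered reads, removal of the trend on GC content and gene length and the fit without the G5DM libraries with high Malat1 (replicates 2 and 3) were chosen after the data were seen. Apart from the counts and the lists of G2/M, G1/S and telomere DNA replication genes given below, 465 results had 12757 values under the alternatives: 11783 kept direction and side of the threshold, 949 kept the direction but no longer passed, 16 newly passed and 9 reversed. Robust moderation and median-ratio scaling moved no count by over 1.5 times, but the values were already close to median-ratio scaling, so the latter could change little. The cause was not tested where none is given. Counts follow the order G1, G3, G5 and the mean for TM against DM, then G3 and G5 against G1 in DM and in TM. A fold of at least 2 left 2285 (G3), 4004 (G5) and 1517 genes (mean), and 3338 and 3654 in TM generations. An adjusted p under 0.01 left 43 (G1) and 2254 (G3), 3 and 3 in DM generations, 3374 and 4018 in TM generations, and 501 and 85 interactions in G5 and G3; both are stricter by construction. Protein-coding genes only gave 44 for G3 against G1 in DM and 199 interactions in G3. A pseudocount of 0.1 gave 3 for G3 against G1 in DM. No filter gave 118 (47 higher, 71 lower) and 75 in DM generations and 1224 and 200 interactions in G5 and G3. A mean FPKM of at least 5, which tests fewer genes, gave 101 (G1), 4576 (G5, 2987 higher and 1589 lower), 4431 (mean), 1 and 2 in DM generations and 3937 and 4134 in TM generations. Quantile normalization gave 408 in G1 (199 higher, 209 lower), and 57 and 16 in DM generations. A fit of only the groups compared, with fewer libraries behind the spread, gave 37 in G1, and 0 (limma, 2784 at an unadjusted p under 0.05 in the fit of all groups) and 2 in DM generations. Sex as a covariate gave 6 for G3 against G1 in DM. It was not run for TM against DM in G3, G3 against G1 in TM and the G3 interaction, where sex coincides with the groups. Voom gave 13 for G3 against G1 in DM and 196 interactions in G3. Rescaling to recovered reads gave 9 and 5 in DM generations, a split of 86 higher and 111 lower in G1, and it turned that of G3 against G1 in TM to 2730 and 3515. It moved the median log2 of all genes by −0.155 for TM against DM in G5, −0.176 and −0.126 for G3 and G5 against G1 in TM and −0.145 for the G5 interaction, the shifts over 0.1 among the scalings. Removal of the trend on GC content and gene length gave 423 in G1 (210 higher, 213 lower), 4031 for G3 against G1 in TM and 1398 interactions in G5. Without the G5DM libraries with high Malat1 the counts were 290 (G1), 2932 (G5), 1348 (248 higher, 1100 lower) and 68 in DM generations, and 351 and 570 interactions in G5 and G3. When each library was left out in turn, the counts ran from 21 to 355 (G1), 1552 to 5336 (G3), 6070 to 8921 (G5) and 5915 to 8669 (mean), 2 to 1533 and 4 to 132 in DM generations, 1775 to 7392 and 2900 to 7683 in TM generations, and 429 to 5756 and 80 to 1088 for the G5 and G3 interactions. A lone library left in a group is assumed to vary like the other groups. Which direction held more genes also turned elsewhere: in G5 with no filter (3936 higher, 4832 lower), rescaling (3575, 4471) and quantile normalization (3911, 3925), in the mean with no filter (3687, 4079) and rescaling (3469, 3843), in G3 with quantile normalization (2100, 2215), for G3 against G1 in TM with the latter (3029, 3144), for G5 against G1 in TM with rescaling (3147, 3531) and quantile normalization (3202, 3398), and without G5DM replicate 1 for G3 and G5 against G1 in DM (329, 1204 and 100, 32).

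The lists of G2/M, G1/S and telomere DNA replication genes were called by other tests. For TM against DM in G5 camera with a preset correlation gave adjusted p of 0.00254, 0.000188 and 0.000101, and fry, which does not compare a list with other genes, 0.0230, 0.00992 and 0.000842. For the mean these were 3.93e-13, 2.99e-13 and 1.08e-09 with camera and 0.000250, 0.000161 and 1.98e-05 with fry, and for G1/S genes in G5 against G1 in DM 0.00196 with camera. With the estimated correlation, leaving out each library gave 0.507 to 0.916, 0.507 to 0.783 and 0.507 to 0.699 in G5, 0.223 to 0.636, 0.200 to 0.636 and 0.200 to 0.572 for the mean, and 0.427 to 0.981, 0.427 to 0.981 and 0.427 to 0.995 for G5 against G1 in DM. The direction in the last comparison reversed without G1DM replicate 1 (0.866, 0.907 and 0.907), without G5DM replicate 3 (G2/M 0.981, telomere 0.995) and without the G5DM libraries with high Malat1 (G2/M 0.936). Direction here is that of the camera test. For the telomere list without G5DM replicate 3, the mean log2 difference stayed positive (0.029, against 0.106 in the main fit). The reversal there lies in the direction of the test and not in the mean. The call of p53-activated genes was lost in G1 with only the groups compared (0.118, range 4.5e-40 to 0.118), in G3 also so (0.208), at a mean FPKM of at least 5 (0.0547) and with rescaling (0.0874), and for the mean with rescaling (0.0502). Cdkn2a reversed for the mean with quantile normalization (−0.18), trend removal (−0.44), without G3TM replicate 1 (−0.065, the lowest of a range up to 0.365 when each library was left out) and without the G5DM libraries with high Malat1 (−0.0065). In G3 it reversed with the replicate block (0.0725) and without G3TM replicate 3 (0.0324, the highest of a range from −1.04 without G3TM replicate 1). With trend removal Egfl7 reversed in G3 against G1 in TM (−0.12, from 0.63), and Lpl in G3 and G5 against G1 in TM (0.12 and 0.18, from −0.75 and −0.76). None of these passed after reversal.

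The labels do not say whether replicate numbers pair DM with TM libraries, and correlations did not settle it. In groups of 2 libraries, centring makes the values mirror images, so G1 and G3 say little. After centring, the correlation across genes between libraries of the same number was 0.042 in G1, −0.341 and −0.292 in G3, and 0.304, 0.319 and −0.018 in G5, where G5DM replicate 3 correlated best with G5TM replicate 2. With the replicate block, 95 genes changed in G1, 3377 in G3, 7539 in G5 and 6761 for the mean, 8 and 5 in DM generations, 5407 and 5936 in TM generations, and 1636 and 159 interactions in G5 and G3. The list p were 0.682, 0.640 and 0.640 in G5, 0.439, 0.439 and 0.368 for the mean, and 0.996, 0.949 and 0.986 for G5 against G1 in DM. At 17448588 to 29571111 recovered reads Wrn lay below the filter on expression, and with no filter it did not pass in any of the planned comparisons (adjusted p 0.155 or more).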

Other observations

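The lists, other classes of genes and libraries described below were picked out after their values were seen. The skeletal muscle, macrophage and leukocyte, type I interferon and mitochondrially encoded lists themselves were fixed before the data were examined. Their tests between groups are given above. No test was run on the other classes or on the contrasts of libraries below. Muscle genes were high in 3 libraries. The mean log2(FPKM + 1) of the skeletal muscle list was 4.43 in G3TM replicate 2, 3.20 in G3TM replicate 3 and 2.79 in G5TM replicate 3, against 0.84 to 1.59 in the other 12. Myog was 61.6, 15.7 and 11.0 FPKM in these 3, and Actc1, a sarcomeric actin gene, was 147, 45.8 and 33.2 FPKM. Acta1 did not follow them, at 82.5, 43.8 and 28.4 FPKM there and up to 178 in G3DM replicate 1.

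Macrophage genes were highest in libraries of the same groups. The macrophage and leukocyte list had a mean of 4.31 in G3TM replicate 3, 2.83 in G5TM replicate 3 and 2.51 in G3TM replicate 2, against 0.60 to 2.23 in the other 12. C1qa, a complement gene, was 64.5, 12.4 and 13.1 FPKM in these libraries, and the lysozyme gene Lyz2 was 233 FPKM in G3TM replicate 3 and 74.9 in G5TM replicate 3, but 27.9 in G3TM replicate 2, below the 33.3, 47.6 and 61.4 of the G5DM libraries. The type I interferon list was highest in G5DM replicates 2 and 3 (means of 2.35 and 2.03, against 0.95 to 1.57 in the other 13). Isg15 was 17.8 and 11.2 FPKM and Stat2 17.1 and 11.7 FPKM in these 2, which also hold the most Malat1. Other members did not follow them: Bst2 was highest in G3TM replicate 3 (37.99 against 24.6 and 25.6 FPKM) and Tmem173 in G1TM replicate 2 (24.8 against 19.6 and 13.2).

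Over 47 ribosomal protein genes of the large subunit (Rpl, with Rps genes left out), the median log2 difference of the 6 G3TM and G5TM libraries from the other 9 was 1.48 (interquartile range 0.89 to 2.28), and 35 were higher without overlap and 0 lower. For 13 mitochondrially encoded protein genes it was −2.10 (−2.43 to −1.67), with 11 lower without overlap, and for 40 histone genes 0.19 (−0.33 to 0.45), with 1 higher and 2 lower. Over all 13562 genes tested it was −0.01 (−0.55 to 0.63), with 2325 higher and 1306 lower without overlap.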
